A study of Mus musculus with 16 samples.

How the data were processed

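Total RNA from bone and brain of C3H/HeJ mice had been converted to biotin-labelled cRNA and hybridized to Illumina one-colour bead arrays, 1 array per mouse. The 16 arrays fell into 4 groups of 4 mice: wild-type bone, Ali35 bone, wild-type brain and Ali35 brain. Bone came from mice aged 120 days and brain from pups aged 3 days, so tissue and age changed together. The labels gave no sex, chip, position or batch.

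The deposited values of each probe were linear intensity values. The submitters' processing notes named GenomeStudio 2011.1. The values themselves showed that background had been subtracted, since values below 0 occurred, and that the arrays had been normalized within each tissue, since the 8 arrays of a tissue had nearly equal quartiles. The method of that normalization was not given in the sources used here. A second, non-normalized table held 16 intensity columns and 16 detection columns under running numbers that matched no label, so these 32 columns were not used. Signal over background was therefore read from the normalized values: on each bone array 47.3% of 25697 probes reached an intensity of 16, and on each brain array 42.3%. For arrays, the number of mice per group limits the precision.

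Of the 25697 probes, 23978 carried 1 gene symbol and 1719 carried none. The Entrez identifiers of 23962 probes were found in a RefSeq gene table of the assembly GRCm38.p6, which was used for names, gene spans and neighbours. Probes were the unit of the tests, and a gene may have several.

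The tests, the gene lists, the rule for naming genes and most alternative settings were chosen before the data were examined. The plan had been to background-correct and normalize the non-normalized table. Because its columns could not be assigned to samples, the planned fallback was followed and the deposited normalized values were tested as they stood. The floor and the filter on dim probes were set after the values had been seen. Values below 16 were set to 16, log2 values were taken, and a probe was kept in a tissue if it reached 16 on at least 4 of the 8 arrays. Each tissue was fitted on its own with limma 3.58.1 (lmFit and eBayes at their defaults, 6 residual degrees of freedom) in R 4.3.3. Ali35 was compared with wild type, and a probe was called changed at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. Errors of log2 changes are limma's moderated standard errors (SE), and errors of intensities are standard deviations (SD) over 4 mice.

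A set of 54 gene lists (34 used for bone, 36 for brain, 16 of them for both) covered pathways and markers of the cell types that each tissue may hold. Each list with at least 5 measured members was tested with camera, from limma, at a preset correlation between genes of 0.01, using the brightest probe of each gene and adjusting over the lists of the tissue. Camera asks whether a list stands apart from the other genes, while fry asks whether its genes moved 1 way on balance, with no comparison to other genes. Members past the threshold were counted both over all probes and adjusted over the list alone.

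Genes were named by rule: the 12 largest rises and 12 largest falls among called probes with 1 symbol, up to 4 members of lowest p in each list, up to 10 genes called in the same direction in both tissues, the 6 genes of lowest p for the difference between tissues, and Xist and Y-linked genes as a check on sex. Any other gene is said to have been chosen after its values were seen. For the difference between tissues, a limma interaction term (the change in bone minus the change in brain) was fitted over all 16 arrays for the 9225 probes kept in both tissues. It used the values normalized within each tissue, although the plan had named a joint normalization, which stands among the alternatives.

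The fits were tested on simulated data built from the spread of the real arrays. Of probes changed 2-fold, 72% were called at the size of the bone comparison (12223 probes) and 90% at that of the brain comparison (10922 probes), and 4.20% and 4.19% of calls were false. Of probes changed 1.41-fold, 32% were called in bone and 42% in brain. Only 50 to 100 probes of each size were changed, far fewer than were called in the real bone data. The values were also drawn independently for each probe and without the floor, so these rates need not hold for the real arrays. Alternatives covered the scaling between arrays, the floor, the filter, the variance model, the threshold, a block by replicate number, an Xist covariate, gene span, the set test and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.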

Results

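Gene expression was profiled with 16 one-colour bead arrays, 1 per mouse, in bone and brain of Ali35 mice and of wild-type mice of the same strain, C3H/HeJ. Ali35 is a mutant mouse line with a mutation in Shc2, a gene for an adaptor protein that links activated receptor tyrosine kinases to Ras. Each of the 4 groups held 4 mice, aged 120 days for bone and 3 days for brain. No probe of the table carried the name Shc2, so the transcript of the mutated gene was not analysed here. After the filter on dim probes, 12223 probes (8700 genes) were tested in bone and 10922 probes (7844 genes) in brain. The arrays of a tissue correlated closely within their groups, with r from 0.977 to 0.991 across probes in bone and from 0.983 to 0.992 in brain.

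Xist and 2 of 4 Y-linked genes set 1 bone array apart. Xist, the RNA that coats the inactive X chromosome and marks female cells, read 221 and 167 on its 2 probes in Ali35 bone replicate 1 and at most 11.7 and 7.17 on the other bone arrays. The Y-linked gene Eif2s3y read -2.50 on that array and 410 to 686 on the others, and Kdm5d read 4.08 against 21.4 to 43.7. The Y-linked genes Uty and Usp9y did not set it apart: Uty read 23.9 there and 22.5 to 37.6 on the others, and Usp9y lay below 0 on all bone arrays. On all brain arrays both Xist probes lay below the floor of 16, and Eif2s3y read 85.8 to 184.

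The bone comparison asked how transcript levels in adult Ali35 bone differ from those in wild-type bone. In Ali35 bone 9 of 17 measured interferon-response genes, 5 of 9 cartilage genes and 6 of 18 bone matrix genes were higher, and the fat cell hormone gene Lep was lower. The 3 lists were called higher by camera, with an adjusted p = 0.72 with an estimated correlation for each. Spen, which encodes a transcriptional co-repressor, rose from an intensity of 25.2 ± 3.64 to 197 ± 18.9 (SD, n = 4 mice per group), a 7.82-fold change (log2 2.97 ± 0.13 SE, adjusted p = 1.30e-05, limma). Oas2, an interferon-induced oligoadenylate synthetase, rose 6.38-fold from 48.4 ± 12.8 to 343 ± 192 (log2 2.67 ± 0.40, adjusted p = 0.00276). Lep fell from 393 ± 152 to 87.4 ± 9.10, a log2 change of -2.10 ± 0.23 (4.29-fold lower, adjusted p = 0.000717). Of 15 measured fat cell genes, Lep was lower and the lipase gene Pnpla2 higher (0.66 ± 0.18), 1 each way adjusted over the list alone too, and the list was not called (median -0.11, camera, adjusted p = 0.791). Adipoq had -0.23 ± 0.18 and did not pass, and Pnpla2 lost its call without 3 of the 8 arrays in turn, with adjusted p up to 0.0632. Sncg, the gene for gamma-synuclein, fell from 708 ± 77.3 to 225 ± 68.9 (log2 -1.70 ± 0.20, adjusted p = 0.001).

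The other largest rises in bone were those of 10 genes. They comprised the oligoadenylate synthetase genes Oas3 (log2 2.42 ± 0.27) and Oasl2 (2.37 ± 0.33), and the zinc finger homeobox genes Zfhx3 (2.44 ± 0.17) and Zfhx2 (2.16 ± 0.17). Atp1b2, a sodium pump subunit, rose by 2.40 ± 0.25. Bcl9l (4.71-fold) and Tcf7l1 (4.50-fold) encode nuclear partners of beta-catenin in Wnt signalling. Cbfa2t3 (4.59-fold) and Atn1 (4.14-fold) encode co-repressors. Mospd3 rose 4.63-fold. Some wild-type arrays lay below the floor of 16 for Mospd3 (3 of 4), Oas3 (2) and Zfhx2 (1), so the size of these 3 rises depends on that floor, most for Oas3 with a wild-type mean of 15.8. Among the falls were Inmt, a methyltransferase gene (log2 -1.65 ± 0.29), Npr3, the clearance receptor for natriuretic peptides (-1.35 ± 0.18), and Adh1, an alcohol dehydrogenase gene (-1.27 ± 0.24). H3f3a, which encodes a histone H3 variant, changed by -1.31 ± 0.30, Yme1l1, a mitochondrial protease gene, by -1.30 ± 0.18, and Mat2b, a regulatory subunit of methionine adenosyltransferase, by -1.30 ± 0.25. Asb3 (-1.56 ± 0.37), Tcte3 (-1.27 ± 0.27), Srp54a (-1.31 ± 0.36) and Ciart, a repressor in the circadian clock (-1.35 ± 0.38), completed the 12. For Ciart 3 Ali35 arrays and 1 wild-type array lay below the floor (means 44.6 and 10.4), and for Yme1l1 and Srp54a 2 and 1 Ali35 arrays did, so the size of these falls depends on the floor as well. The groups did not overlap for any of these 24 genes except Ciart, and 22 of the 24 were still called whichever array was left out. The exceptions were Srp54a and Ciart, whose calls were lost in 3 and 7 of the 8 cases, with adjusted p up to 0.0738 and 0.0745. Another probe was tested for 9 of the 24 genes and passed in the same direction for 7, but not for Asb3 (-0.25) and Yme1l1 (-0.12).

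**Figure D1:**
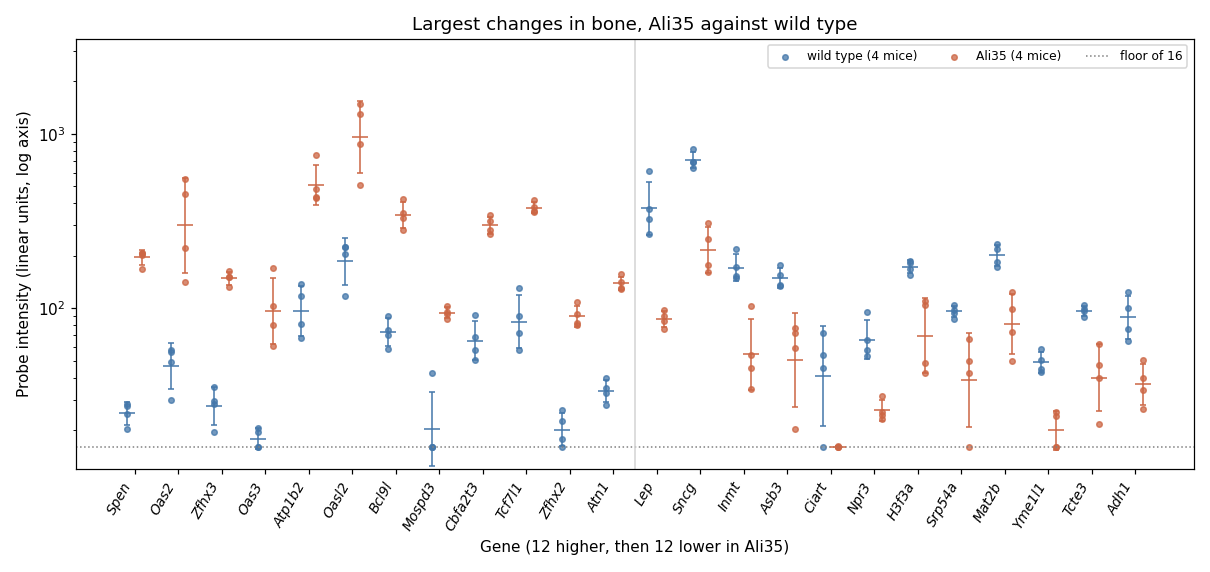
Probe intensity on a log axis for the 12 genes with the largest rise and the 12 with the largest fall in Ali35 bone, 1 point per mouse (4 wild type, 4 Ali35). Horizontal marks and bars give the mean and SD of the log2 values, and values below 16 are drawn at the floor of 16.

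In bone, 3006 probes changed (24.6%), 1552 of them higher in Ali35 (1242 genes) and 1454 lower (1158 genes). The median change of the called probes was 1.51-fold, 285 probes rose and 77 fell by at least 2-fold, and 187 called probes had no gene symbol. The 4 arrays of each genotype did not overlap for 28.7% of probes, against 2.86% by chance. The number of calls fell to 1759 without wild-type replicate 1, to 1634 without wild-type replicate 4 and to 1430 with no filter on dim probes. Without Ali35 replicate 1, the array with the Xist signal, it was 2572.

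Among the gene lists in bone, the interferon response list was called higher: 9 of its 17 measured genes were higher, 13 adjusted over the list alone, with a median log2 change of 0.83 (camera, adjusted p = 8.21e-05, and adjusted p = 0.72 with an estimated correlation). Besides Oas2 and Oasl2, these included Lgals3bp, a secreted scavenger receptor protein (2.50-fold, log2 1.32 ± 0.17), and Rsad2, the antiviral enzyme viperin (1.51-fold, log2 0.59 ± 0.10). Without Ali35 replicate 1 the list had an adjusted p of 0.000633. All 9 measured cartilage genes had positive values, 5 of them rose (5 adjusted over the list alone), and the list was called higher (median 0.94, adjusted p = 0.00207, and adjusted p = 0.72 with an estimated correlation). Col2a1, the main collagen of cartilage, rose from 1431 to 5375 (log2 1.97 ± 0.27), the cartilage proteoglycan gene Acan rose by 1.89 ± 0.29, the matrix protein gene Chad by 1.71 ± 0.18 and Comp by 0.56 ± 0.13.

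Of 18 measured osteoblast and bone matrix genes, 6 rose (6 adjusted over the list alone), and the list was called higher (median 0.22, camera, adjusted p = 0.0235, and adjusted p = 0.72 with an estimated correlation). They included Col1a1, the main collagen chain of bone, at 3.76-fold (log2 1.91 ± 0.23, from 2974 to 10916), Sp7, a transcription factor of osteoblasts (1.06 ± 0.11), the alkaline phosphatase gene Alpl (1.04 ± 0.20) and Col5a1 (0.57 ± 0.12). Abundant bone genes chosen after their values were seen did not pass: Sparc had 0.23 ± 0.16, Ibsp 0.13 ± 0.17 and the osteocalcin gene Bglap -0.22 ± 0.20. The osteoclast list was called higher, with 5 of 13 genes higher (6 higher and 1 lower adjusted over the list alone), at an adjusted p of 0.0440, and adjusted p = 0.72 with an estimated correlation. Its members of lowest p were the gelatinase gene Mmp9 (0.76 ± 0.12), which also stands in the neutrophil list, Nfatc1, the master transcription factor of osteoclasts (0.86 ± 0.17), the proton pump gene Tcirg1 (0.70 ± 0.16) and the receptor gene Oscar (0.53 ± 0.16). The skeletal muscle list was called higher, with 5 of 28 genes higher (3 adjusted over the list alone), at an adjusted p of 0.0440, and adjusted p = 0.80 with an estimated correlation. Ryr1, the calcium release channel of muscle, rose by 1.32 ± 0.20, the myosin gene Myh4 by 1.05 ± 0.21, Actn3 by 0.73 ± 0.19 and the calcium pump gene Atp2a1 by 0.43 ± 0.13.

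Both lists called lower in bone encode housekeeping machinery. Of 25 genes for cytosolic ribosomal proteins, 8 fell (9 adjusted over the list alone), with a median of -0.11 (camera, adjusted p = 0.0235, and adjusted p = 0.72 with an estimated correlation). The members of lowest p were Rpl22 (-0.50 ± 0.12), Rpl12 (-0.43 ± 0.11), Rps15 (-0.40 ± 0.11) and Rpl30 (-0.45 ± 0.12). Of 30 genes for mitochondrial oxidative phosphorylation, 2 fell (2 adjusted over the list alone), Atp5pb of the ATP synthase (-0.76 ± 0.19) and Ndufa4 (-0.41 ± 0.10), and the list median was -0.20 (adjusted p = 0.0199, and adjusted p = 0.72 with an estimated correlation). In this list and the muscle list the share of members called was below the 24.6% of all probes tested in bone.

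**Figure D2:**
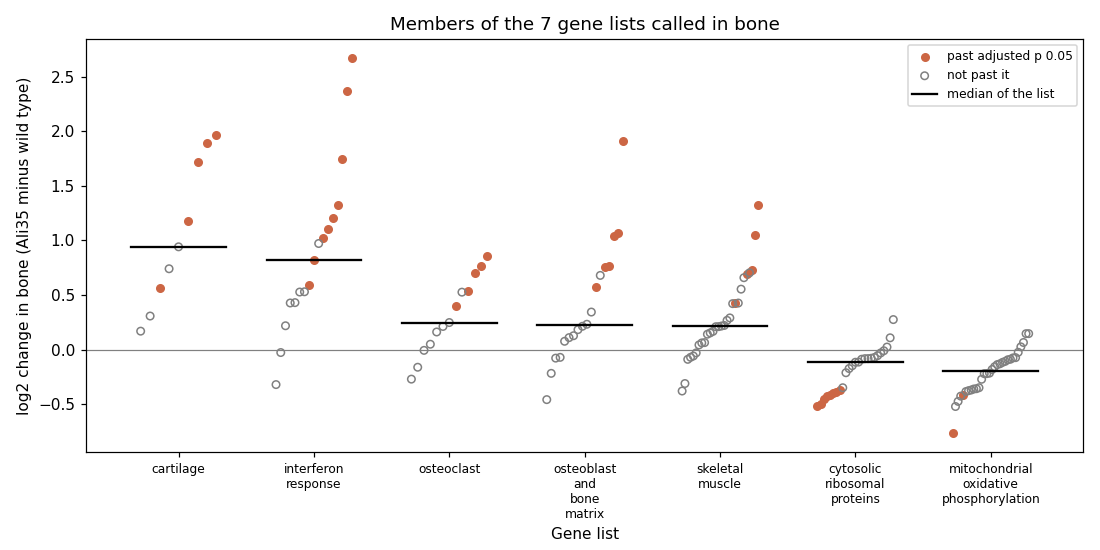
Log2 change in bone (Ali35 minus wild type, linear axis) of each measured member of the 7 called gene lists, 1 point per gene, with the list median as a black line. Filled points passed an adjusted p of 0.05 over all probes: 5 of 9 in cartilage, 9 of 17 in the interferon response and 2 of 30 in oxidative phosphorylation.

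The 7 calls were made among 32 lists tested in bone, 0 were called with an estimated correlation (0 also at an unadjusted p under 0.05), and 15 of the 35 ways of dividing the 8 bone arrays into 4 and 4 gave as many, up to 14. Fry, which asks whether the genes of a list moved 1 way on balance and not whether they moved more than other genes, called 4. Leaving out single arrays kept the interferon and cartilage calls and ended the other 5. The osteoblast list had an adjusted p of 0.0841 without wild-type replicate 2, 0.0778 without wild-type replicate 3 and 0.218 without Ali35 replicate 1. The muscle list had 0.107, 0.0778 and 0.0674 without wild-type replicates 2, 3 and 4, and 0.284 and 0.117 without Ali35 replicates 1 and 4. The osteoclast list had 0.0778 and 0.0651 without wild-type replicates 3 and 4, and 0.172, 0.0561 and 0.0503 without Ali35 replicates 1, 2 and 4. The ribosomal list had 0.0722 without wild-type replicate 3 and 0.128 without Ali35 replicate 1, and the oxidative phosphorylation list had 0.0893 without Ali35 replicate 2. With all arrays but the gene span trend removed, the ribosomal list had 0.278. The number of lists called fell to 3 without wild-type replicate 3 and to 3 without Ali35 replicate 1. Of the list members named above, Actn3, Atp2a1, Oscar, Rpl12, Rpl22, Rpl30, Rps15, Atp5pb and Ndufa4 lost their calls without at least 1 array, with adjusted p up to 0.110 for Atp2a1.

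Genes close to Shc2 in function were examined in bone as well. Of 9 measured genes of the Shc family and its partners, 3 rose (3 adjusted over the list alone): Irs2, an insulin receptor substrate (2.86-fold, log2 1.52 ± 0.27), and the adaptor genes Gab1 (0.49 ± 0.13) and Sh2b1 (0.45 ± 0.13). The list was not called (camera, adjusted p = 0.279). Among 9 receptor tyrosine kinases, Igf1r rose by 1.12 ± 0.30 and the neurotrophin receptor gene Ntrk2 fell by 0.53 ± 0.17 (2 higher and 1 lower adjusted over the list alone), and the list had an adjusted p of 0.369. Of 10 Ras-ERK response genes, Dusp4 (0.49 ± 0.11) and Phlda1 (0.43 ± 0.12) rose (2 adjusted over the list alone), and the list had an adjusted p of 0.775. Igf1r, Ntrk2, Sh2b1 and Phlda1 lost their calls without at least 1 array, with adjusted p up to 0.127 for Ntrk2. In the kinase and Ras-ERK lists the share of members called was below the 24.6% of all probes tested in bone.

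The brain comparison asked the same question in pups. Of the called probes, 208 were higher and 190 lower in Ali35, with a median change of 1.5-fold. R3hdm1, which encodes an RNA-binding protein, rose from 47.8 ± 7.90 to 114 ± 17 (SD, n = 4 mice per group), a 2.39-fold change (log2 1.25 ± 0.15 SE, adjusted p = 0.00754, limma). Flrt2, a cell adhesion and guidance gene, rose 1.99-fold from 42.8 ± 3.05 to 85.6 ± 9.67 (log2 0.99 ± 0.11, adjusted p = 0.00754). Lamtor2, part of the complex that recruits mTOR to lysosomes, fell from 97.2 ± 8.17 to 43.2 ± 8.0 (log2 -1.19 ± 0.14, adjusted p = 0.00754). Tkt, the transketolase of the pentose phosphate pathway, fell from 672 ± 130 to 341 ± 49.9 (log2 -0.97 ± 0.15, adjusted p = 0.0174).

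Further rises in brain were those of the chromatin and transcription genes Mllt3 (log2 1.27 ± 0.17), Mier1 (1.15 ± 0.13), Arid5b (1.10 ± 0.16), Bach1 (1.33 ± 0.25) and Zfp326 (1.01 ± 0.14). Mef2c, a transcription factor of developing neurons, rose from 83.9 ± 21.3 to 189 ± 42.1 (log2 1.18 ± 0.20). The RNA helicase gene Ddx17 rose by 1.05 ± 0.14, the actin-binding protein gene Afap1 by 1.08 ± 0.15 and the Golgi matrix gene Golga2 by 1.34 ± 0.30. Nsd1, a histone methyltransferase gene, was at the floor on all wild-type arrays and at least 1.99-fold higher in Ali35. The largest fall was that of Ptpre, a tyrosine phosphatase gene (3.03-fold lower, log2 -1.60 ± 0.32). Alas2, the first enzyme of haem synthesis in red cells, changed by -1.19 ± 0.28, the imprinted gene Mest by -1.08 ± 0.23, Ndufb6 of respiratory complex I by -1.07 ± 0.23, and the glycolytic gene Tpi1 by -0.84 ± 0.17. Klhdc3 (-1.17 ± 0.19), AI837181 (-0.93 ± 0.20), Nabp2 (-0.92 ± 0.21), Peli1 (-0.85 ± 0.13) and Foxj2 (-0.84 ± 0.16) completed the 12. The sizes for Ddx17, Mier1, Mest and Nabp2 depend on the floor, with 2 and 1 wild-type arrays and 2 and 1 Ali35 arrays below it. The groups did not overlap for any of the 24 genes. Another probe was tested for 14 of the 24 genes, and for 12 of them none passed in the same direction: a second Ptpre probe had 0.26 (adjusted p = 0.133), a second Ndufb6 probe 0.04, a second Mier1 probe -0.04, 3 further Golga2 probes lay between -0.67 and -0.10, and 2 further Tkt probes had -0.20 and 0.12. The other 7 were Mllt3, Mef2c, Ddx17, Mest, Nabp2, Peli1 and Tpi1.

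**Figure D3:**
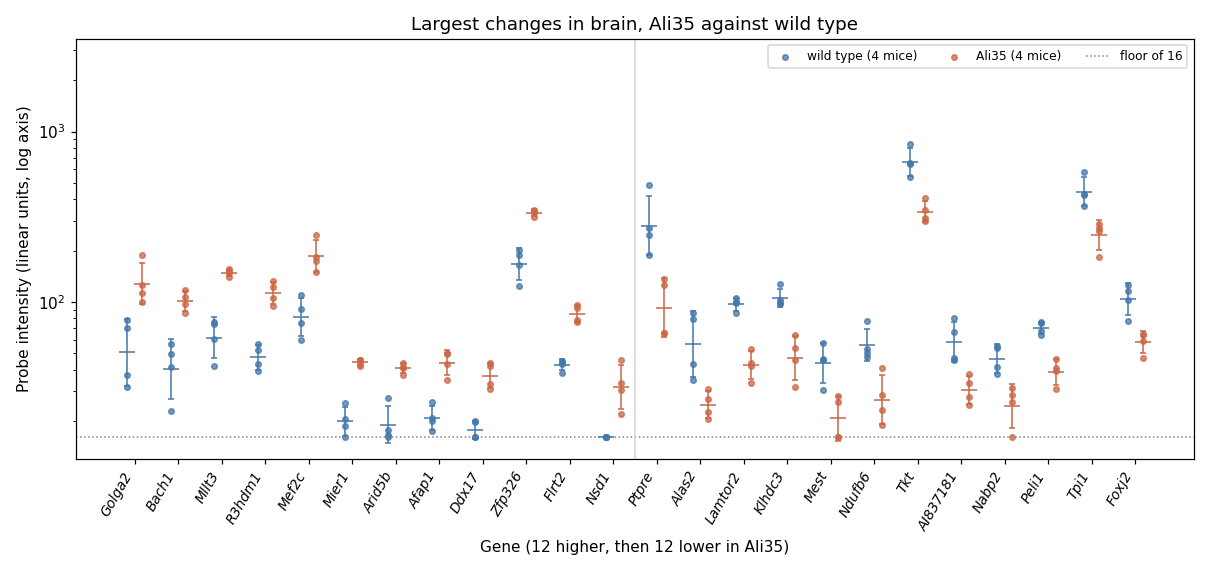
Probe intensity on a log axis for the 12 genes with the largest rise and the 12 with the largest fall in Ali35 brain, 1 point per mouse (4 wild type, 4 Ali35). Horizontal marks and bars give the mean and SD of the log2 values, and values below 16 are drawn at the floor of 16.

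The only list called in brain was that of the oligodendrocyte lineage, the cells that make myelin. It was lower: 12 of its 13 measured genes had negative values, 1 of them fell (3 adjusted over the list alone), and the median was -0.28 (camera, adjusted p = 0.00140, and adjusted p = 0.54 with an estimated correlation). Cnp, an enzyme of myelin-forming cells, fell by 0.54 ± 0.12 on the log2 scale, while a second, dimmer Cnp probe had -0.23 and did not pass. The members next in p did not pass over all probes: the precursor cell receptor gene Pdgfra had -0.48 ± 0.12, and the myelin genes Mobp and Mbp had -0.74 ± 0.20 and -0.69 ± 0.25. The value of Mobp depends on the floor, since 3 of its 4 Ali35 arrays lay below it (means 29.1 and 10.4). The call was kept whichever array was left out, with an adjusted p of at most 0.0282, but 21 of the 35 ways of dividing the brain arrays gave at least 1 list, up to 6.

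Of 9 erythroid genes in brain, Alas2 fell (4 lower and 1 higher adjusted over the list alone), while the haemoglobin genes Hba-a1 (-0.95 ± 0.24, from 8628 to 4523, adjusted p = 0.0532) and Hbb-b2 (-1.12 ± 0.34, adjusted p = 0.0878) did not pass, and the list was not called (camera, adjusted p = 0.130). Single members of other brain lists also passed. The neuropeptide gene Pmch (0.52 ± 0.13), the transcription factor genes Isl1 (0.46 ± 0.11) and Lhx1 (0.53 ± 0.12) and the stem cell gene Sox2 (0.47 ± 0.11) were higher. The astrocyte filament gene Gfap (-0.58 ± 0.13), the mitotic gene Nusap1 (-0.57 ± 0.12) and Ndufb3 (-0.63 ± 0.10) were lower. Of the 10 measured genes of the Shc family and its partners, 0 passed in brain by limma, 0 also adjusted over the list alone, while 3 had an unadjusted p under 0.05, and the list had an adjusted p of 0.636.

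In brain, 398 of 10922 probes changed (3.64%), 208 higher in Ali35 (186 genes) and 190 lower (174 genes), and 2574 had an unadjusted p under 0.05. The groups did not overlap for 15.7% of probes, against 2.86% by chance, and 11 probes rose and 6 fell by at least 2-fold. The count depended on every array: 52, 192, 105 and 43 probes were called without wild-type replicates 1 to 4, and 114, 130, 174 and 245 without Ali35 replicates 1 to 4. With no filter on dim probes it was 19. Of the 24 genes with the largest changes, 10 were still called whichever array was left out: R3hdm1, Flrt2, Mllt3, Mier1, Arid5b, Afap1, Ddx17, Zfp326, Lamtor2 and Tkt. The other 14 and all single list members named lost their calls without at least 1 array, with adjusted p up to 0.126 for Alas2.

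The comparison of the tissues asked whether the line changed the same genes in bone and brain. The overlap was no larger than that of independent lists. Of the 9225 probes tested in both, 17 were higher in both (18.2 for independent lists) and 16 lower in both (19.4), and 31 were called in opposite directions (37.9). Across probes, which are not independent replicates, the log2 changes had a Pearson correlation of -0.01 and a Spearman correlation of -0.03. The shared genes of lowest p included Tmem94, which was higher in bone by 1.30 ± 0.16 and in brain by 0.80 ± 0.11. The histone acetyltransferase gene Ep300 was higher by 1.03 ± 0.14 and 0.59 ± 0.12, the Rac activator gene Prex1 by 1.07 ± 0.17 and 0.40 ± 0.09, and the transcriptional repressor gene Bcl6 by 0.49 ± 0.10 and 0.51 ± 0.11. Synrg (0.61 and 0.93), Fbrsl1 (1.00 and 0.45), Plpp3 (0.55 and 0.46) and Gmip (0.55 and 0.46) were higher in both. Tfam, which maintains mitochondrial DNA (-0.51 ± 0.11 and -0.58 ± 0.11), and Lyrm2 (-0.57 and -0.70) were lower in both. Of these 10 genes 5 had another probe, which passed in brain for 0 of them: in bone and brain it had -0.01 and -0.49 for Plpp3, -0.54 and 0.34 for Lyrm2, -0.63 and -0.12 for Tfam, 0.52 and 0.40 for Synrg and 0.54 and 0.22 for Gmip. In bone the other Plpp3 probe lay below the floor on 2 arrays of each genotype (means 13.7 and 13.4), so its -0.01 rests on the floor. In brain, all of the 10 genes except Tmem94 lost their calls without at least 1 array, with adjusted p up to 0.111.

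**Figure D4:**
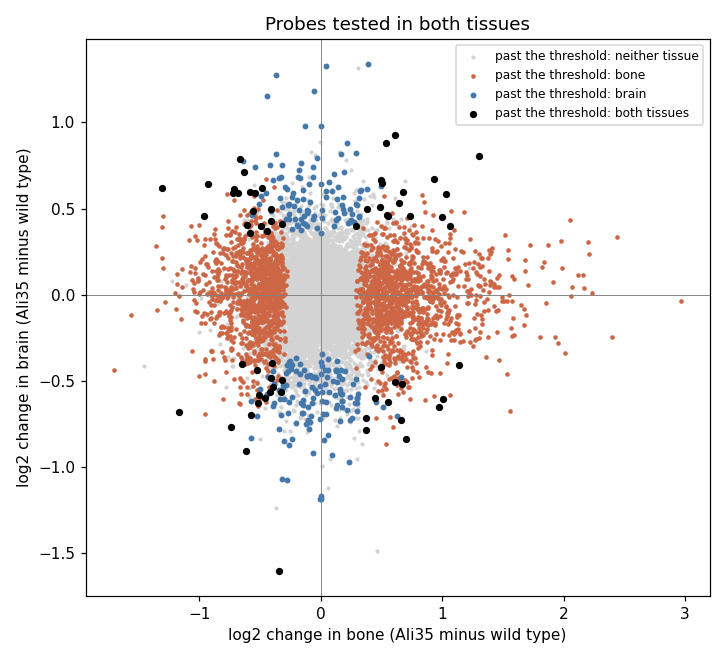
Log2 change in brain against log2 change in bone (Ali35 minus wild type) for the 9225 probes tested in both tissues, coloured by the tissue in which they passed an adjusted p of 0.05. Of the probes called in both, 33 lie in the same direction and 31 in opposite directions.

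The difference of the change between the tissues was itself tested. It passed for 2255 of 9225 probes (24.4%, limma interaction), 1188 with a larger value in bone and 1067 with a smaller value in bone. The genes of lowest p had large rises in bone and small or negative values in brain. Ttyh3, a chloride channel gene, had 2.01 in bone and -0.34 in brain (difference 2.35 ± 0.20, adjusted p = 4.08e-06). Zc3h3, an RNA export gene, had 1.93 and -0.24 (2.17 ± 0.19), Zfhx2 had 2.16 and 0.11 (2.05 ± 0.19), and Wiz, a partner of histone methyltransferases, had 1.85 and -0.05 (1.90 ± 0.16). Fhod1, an actin regulator gene, had 0.98 and -0.65 (1.63 ± 0.15), and Atxn2, an RNA-binding protein gene, had 1.26 and -0.14 (1.40 ± 0.13). For Fhod1 3 Ali35 brain arrays, and for Zc3h3 1 wild-type bone and 2 Ali35 brain arrays, lay below the floor, as did 1 wild-type bone array for Zfhx2, so the size of these 3 differences depends on it. The lists tested for a difference were those used for both tissues. The osteoblast list, called in bone, and the oligodendrocyte list, called in brain, were added, although each was set for 1 tissue. Of 17 lists tested, 4 differed between the tissues: the interferon response (8 genes, medians 0.53 and -0.05, camera, adjusted p = 0.0312), the osteoblast and bone matrix list (5 genes, 0.76 and -0.06, adjusted p = 0.0319), the erythroid list (9 genes, 0.08 and -0.09, adjusted p = 0.0227) and the ribosomal list (25 genes, -0.11 and 0.04, adjusted p = 0.0227). The 5 bone matrix genes were part of the 18 measured in bone, whose median there was only 0.22. Each of the 4 lists had an adjusted p = 0.51 with an estimated correlation. Tissue and age changed together, so these differences cannot be assigned to either, and 16 of 100 drawn pairs of array divisions gave as many lists, up to 8.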

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

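The tests of an array of the other sex, gene span, macrophages, osteoblasts, muscle and cartilage were chosen only after the result was seen, and the divisions of arrays list by list were added once the total for all lists was known.

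The change in bone was broad, with 3006 of 12223 probes called. Chance is argued against as the source of that number: of the 35 divisions of the 8 arrays into 4 and 4, 1 gave as many, the real one, and the highest of the others gave 5. The smallest exact p that 35 divisions can reach is 0.0286, so they cannot exclude chance. An array of the other sex as the main cause is argued against by the 2572 probes called without Ali35 replicate 1, and a trend with the genomic span of the gene by the 2699 called after each array's trend was removed (94.2% of probes had a span). Trends with transcript length or GC content could not be tested, and no batch was given in the labels. The genotype stays open as a candidate explanation, beside any other difference between the mice of the groups, such as cage, litter or day of preparation.

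The interferon response list was called higher in bone, with 9 of 17 genes higher and a median of 0.83. An array of the other sex is argued against, since without Ali35 replicate 1 the adjusted p was 0.000633 (1.21e-06 to 0.72 over all settings, the highest being the adjusted p = 0.72 with an estimated correlation). More monocytes and macrophages in the sample are argued against as well: the median of that list was -0.027 with an SD of 0.28 over 14 genes, none of which stands in another list. Its most abundant genes, chosen after their values were seen, were Vcam1 (5172 to 4722) and Lgmn (1558 to 1599). Of the 14, 2 were called higher, Cx3cr1 and Fcgr1 (limma, adjusted p = 0.0275 and 0.0445), and 0 lower. Adjusted over the list alone, 0 passed. Chance could not be excluded for this list, because 11 of the 35 divisions gave as small a camera p (real 2.57e-06, lowest of the others 5.53e-14). The rise may reflect the genotype, or a state such as an infection that differed between individual mice, which was not tested.

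In bone 6 of 18 bone matrix genes, 5 of 28 muscle genes and 5 of 9 cartilage genes were higher, and of all measured members only Mmp13 (-0.07), which did not pass, stood in another list too. Whether more osteoblasts were the source of the whole 1.91 of Col1a1 cannot be decided here. Col1a1 was set against its list as the member with the largest rise, so the others lay below it by construction. The other 17 measured members of the list had a median of 0.21 with an SD of 0.44, from -0.46 for Omd to 1.06 for Sp7. Of these, 2 (Sp7 and Alpl) reached 1 in 2 of the Col1a1 value or more. The same holds for more skeletal muscle and the 1.32 of Ryr1, the largest rise of the muscle list. The other 27 members had a median of 0.21 with an SD of 0.33, from -0.38 for Tcap to 1.05 for Myh4. Of these, 4 (Myh4, Actn3, Ttn and Tnnc1) reached 1 in 2 of the Ryr1 value or more. The flat values of the brightest members, Bglap2 (19041 and 18224) and Pvalb (27476 and 28879), are no evidence here, though the medians include them. The highest reading of a bone array was 30547.5 to 38607.9, and rises as large as those of Col1a1 and Ryr1 would have passed it. Whether other bright members were held down in this way was not tested. More cartilage in the sample could account for the cartilage values, as 9 of 9 were positive, with Col2a1 at 1431 and 5375 and Chad at 1191 and 3817. This rule, the share of positive values, was not the one used for the osteoblast and muscle lists. There 14 of 18 and 22 of 28 values were positive, so the outcomes cannot be set against each other. An increase of osteoblasts or muscle and a change of transcription within these cells stay open. Chance could not be excluded for any of the 3 lists: 14 divisions gave as small a camera p for osteoblasts (real 0.00367, lowest of the others 2.19e-09), 18 for muscle (0.00962, 5.39e-14) and 7 for cartilage (0.000129, 1.14e-07), each of 35.

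For the other called lists chance could not be excluded either. As small a camera p came from 13 of 35 divisions for oxidative phosphorylation (real 0.00186, lowest of the others 1.51e-07), 10 for ribosomal proteins (0.00365, 6.06e-05), 6 for osteoclasts (0.00861, 8.33e-05) and, in brain, 7 for the oligodendrocyte lineage (4.38e-05, 6.36e-09). As many lists in all came from 15 of the 35 divisions in bone (real 7, highest of the others 14) and 21 in brain (real 1, highest of the others 6). For the 398 probes changed in brain chance is argued against but not excluded, since 1 of 35 divisions gave as many and the highest of the others gave 1. The smallest exact p that these divisions can reach is 0.0286, and the number fell to 43 to 245 when an array was left out.

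A gap between 1 mouse and the other 3 of its group, divided by the range of the group, exceeded Dixon's critical value at the 95% level in 7 of 108 groups of 4 checked. Chance alone would give about 1 in 20, but the 2 shares are not alike. Groups with all 4 readings set to the floor, such as Xist in brain and Nsd1 in wild-type brain, could not exceed the value. The flags of Xist and Eif2s3y also came from 1 array. Spen in Ali35 bone had a ratio of 0.893, with 168 in replicate 1 against 203 to 208. Oasl2 in wild-type bone had 0.852, with 117 in replicate 4 against 204 to 225. Mospd3 in wild-type bone had 1, with 42.4 in replicate 3 and the others at the floor. Ciart in Ali35 bone had 1 only because 3 readings, 1.46 to 15.3, were set to the floor below the 16.3 of replicate 4. The Xist probes in Ali35 bone had 1 and 1, and Eif2s3y had 0.950, all from replicate 1 with readings of 221, 167 and -2.50. On linear readings without the floor, taken after the values were seen, 5 of the 7 stayed above the critical value, while Ciart had 0.477 and Oasl2 0.808.

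The change in bone minus that in brain differed from 0 by the interaction test for Ttyh3 (2.35), Wiz (1.90), Zc3h3 (2.17), Fhod1 (1.63), Atxn2 (1.40) and Zfhx2 (2.05). The same test passed for 2255 probes, and 1 of 100 drawn pairs of divisions, the real one, gave as many. Pairs with other bone divisions gave at most 10, so the draw tested mainly the change in bone. Only 2 of the other pairs held the real division of the bone arrays, and they gave 1210 and 908. With 2 such pairs chance cannot be excluded for the number of probes that differ between the tissues. The lists that differed between the tissues were the interferon response (adjusted p = 0.0312), ribosomal proteins (0.0227), erythroid cells (0.0227) and bone matrix (0.0319). The bone matrix list had been set for bone alone and was called there, so its difference is no separate result. For these 4 lists chance could not be excluded, because 16 of 100 pairs gave as many and the highest of the others gave 8.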

How the results depend on the processing

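Quantile normalization within the tissue, a floor and filter at 50, log2 of the value plus 16, a filter of 16 on all 4 arrays of a genotype and the removal of the gene span trend were chosen only after the data were seen. No result reversed under any setting, and no probe called in bone or brain changed sign. Of the named genes under settings other than leaving out an array, 2049 pairs of gene and setting in bone kept the side of the threshold, 150 lost the call and 63 gained one, and in brain 1890, 116 and 97. Leaving out arrays lost 172 and 188 such calls.

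In bone, the probes changed, higher and lower were 1430, 803 and 627 with no filter on dim probes, and 1539, 936 and 603 with a fold change of at least 1.5. The lower ones were 2198 with one fit over all 16 arrays and 2204 with adjusted p under 0.10. Leaving out an array gave 1634 to 2636 changed, 955 to 1415 higher and 679 to 1251 lower. The Xist covariate gave 2572, the same as leaving out Ali35 replicate 1, since Xist lay above the floor on that array alone. It is therefore no separate check on sex. The replicate block gave 2335. Arrays of the same replicate number correlated weakly across genotypes (-0.12 to 0.16 in bone, 0.01 to 0.14 in brain). On the second main axis of variation (principal component 2, 19.4% of the variance in brain), brain replicates 1 and 2 of both genotypes lay at 3.32 to 12.4. Brain replicates 3 and 4 lay at -18.9 to -2.95. In bone replicate 2 lay at 1.30 in wild type and -26.7 in Ali35. A batch shared by replicate number therefore stays open in brain.

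In brain, the same 3 counts were 224, 126 and 98 with all 16 arrays normalized together, 19, 14 and 5 with no filter, 850, 428 and 422 for the variance with trend and robust, and 947, 481 and 466 for one fit over all 16 arrays. They were 104, 61 and 43 with a plain t statistic, 1081, 548 and 533 with adjusted p under 0.10, 197, 104 and 93 with a fold change of at least 1.5, and 206, 103 and 103 with the replicate block. A floor and filter at 50 gave 640 with 329 lower, and log2 of the value plus 16 gave 295 lower. Leaving out an array gave 43 to 245 changed, 27 to 123 higher and 12 to 122 lower. No filter adds probes without signal to the adjustment (25697 tested). It also adds them to the estimate of variance shared across probes, with most of their values set to the floor. How much each of these lowered the count was not tested. The wider and narrower thresholds pass more and fewer probes by construction, and a left-out array lowers the number of mice. For the other settings the cause was not tested.

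The lists called in bone were 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 4 with fry, and 3 to 8 when an array was left out. Fry, which does not compare a list with other genes, called cartilage and osteoclasts, and also megakaryocytes and RANKL and inflammatory cytokines. In brain they were 0 and 0 (fry, 11 at an unadjusted p under 0.05). Muscle also lost its call with cyclic loess, quantile normalization and a floor of 50 (adjusted p 0.0502, 0.0537 and 0.0531), osteoclasts with all 16 arrays normalized together and a floor of 50 (0.0521 and 0.0733), and ribosomal proteins without the span trend (0.278). Calls were gained by megakaryocytes with no filter and without the span trend (0.0193 and 0.0415), by endothelial cells with no filter (0.0123) and by the hypoxia response without wild-type bone replicate 1, each with an adjusted p = 0.72 with an estimated correlation in the main setting. With no filter 1 probe was called in the same direction in both tissues, against 33. For the difference of the genotype effect between bone and brain, the count stayed within 1.5 times of 2255 in all settings run, at 1746 to 2250 when an array was left out. Not run were the alternatives that needed the unassigned table (background correction, offset 50, detection filter), a chip block, since no chip was named, and an Xist covariate in brain, where Xist lay at the floor.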

Other observations

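The tests of gene families were chosen only after the data were seen, and the lists and the genes beside Shc2 were set before. Several lists that camera did not call in bone held called members. Such members alone do not set a list apart, since 24.6% of all probes tested in bone were called. Of 12 genes of megakaryocytes and platelets, 6 rose and 1 fell (6 and 1 adjusted over the list alone): Vwf, the adhesion protein of vessel walls and platelets, rose by 1.11 ± 0.11, Selp by 0.91 ± 0.19, Gp5 by 0.50 ± 0.10 and F2rl2 by 0.48 ± 0.10 (camera, adjusted p = 0.119). Camera called this list with no filter on dim probes (0.0193) and with the gene span trend removed (0.0415), while the main setting gave an adjusted p = 0.72 with an estimated correlation. Fry, which asks whether the genes of a list moved 1 way on balance and does not compare them with other genes, gave 0.0281. Of 15 endothelial genes, 4 rose (4 higher and 1 lower adjusted over the list alone), among them Eng by 1.02 ± 0.13, Robo4 by 0.75 ± 0.14, Cdh5 by 0.72 ± 0.13 and Sox18 by 0.69 ± 0.11 (adjusted p = 0.0924, 0.0123 with no filter on dim probes, and adjusted p = 0.72 with an estimated correlation). Of 16 genes of B lymphocytes, the antigen presentation gene Cd74 rose by 1.10 ± 0.15, while Cd79b (-0.55 ± 0.13), Rag1 (-0.59 ± 0.14) and Blk (-0.58 ± 0.15) fell, with 2 higher and 4 lower in all (2 and 6 adjusted over the list alone, adjusted p = 0.279). Of 9 genes of eosinophils and mast cells, 3 fell (1 higher and 4 lower adjusted over the list alone), Ear10 by 0.73 ± 0.17, the IgE receptor gene Fcer1a by 0.63 ± 0.12 and Cpa3 by 0.51 ± 0.12 (adjusted p = 0.285).

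Of 17 genes for RANKL and inflammatory cytokines, 4 fell (4 adjusted over the list alone): Il1a, the gene for interleukin 1 alpha, by 1.21 ± 0.13, Il18 by 0.59 ± 0.13, Nfkbia by 0.53 ± 0.15 and Tlr4 by 0.42 ± 0.11 (camera, adjusted p = 0.279, and 0.0434 by fry, which is no comparison with other genes). Of 13 clock genes, Nr1d1 rose by 0.78 ± 0.15 while Dbp fell by 1.18 ± 0.25, Nr1d2 by 0.78 ± 0.19 and Ciart by 1.35 ± 0.38 (1 higher and 3 lower adjusted over the list alone, adjusted p = 0.916). The size for Ciart depends on the floor, with 3 of 4 Ali35 arrays below it. Of 17 erythroid genes, 4 rose (3 adjusted over the list alone), including the membrane skeleton genes Ank1 (1.27 ± 0.17) and Sptb (0.97 ± 0.23), and the list had an adjusted p of 0.451. Of 21 genes of BMP and TGF-beta signalling, Tgfb1 rose by 1.37 ± 0.18, Tgfbi by 0.46 ± 0.11 and Ltbp1 by 0.43 ± 0.14, and Id1 fell by 0.63 ± 0.15 (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.765). Among the members named here, Sptb, Blk, Id1 and Nr1d2 lost their calls without 1 array, and Tlr4, Nfkbia, Ltbp1 and Ciart without several, with adjusted p up to 0.118 for Ltbp1. In the cytokine, erythroid and BMP lists the share of members called was below the 24.6% of all probes tested in bone. For 4 lists in bone and 6 in brain, none of them called, the signs of median, mean and test differed.

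Genes were also grouped by the stem of their symbols, giving 94 families of 10 or more genes in bone. Of these, 7 were called by camera, while in brain 0 of 73 families were. Families were not tested on array divisions, with arrays left out or with the span trend removed. The stems Col, Rps and Rpl share genes with the lists above, so their calls are no separate evidence. A stem may also take in genes outside the family that it stands for. Higher were 12 of 20 genes with the collagen stem Col (median 0.71, adjusted p = 2.02e-05, and adjusted p = 0.66 with an estimated correlation). So were 7 of 11 with the semaphorin stem Sema (median 0.56, adjusted p = 0.00992, and adjusted p = 0.66 with an estimated correlation). Of 10 genes with the stem Irf, which is not held by interferon regulatory factors alone, 4 were higher (median 0.38, adjusted p = 0.0260, and adjusted p = 0.66 with an estimated correlation). Lower were 13 of 40 genes with the stem Mrpl of large mitochondrial ribosomal proteins (median -0.25, adjusted p = 0.000101, and adjusted p = 0.66 with an estimated correlation). So were 11 of 25 with the stem Rps of small cytosolic ribosomal proteins (adjusted p = 0.00522, and adjusted p = 0.66 with an estimated correlation). With the stem Rpl of large cytosolic ribosomal proteins 5 of 33 were lower (adjusted p = 0.0419, and adjusted p = 0.73 with an estimated correlation), and of the Nudt hydrolases 2 of 16 (adjusted p = 0.0416, and adjusted p = 0.66 with an estimated correlation).

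A local change around the mutated gene was tested on the 50 genes on each side of Shc2, a test written down before its result was seen. In bone 11 of the 47 measured neighbours were called (23.4%), against 27.6% of the other genes (Fisher's exact test, two-sided p = 0.624). In brain 3 of 44 were called (6.82%), against 4.58% of the others (exact p = 0.454). The shares lay on different sides of the other genes in the tissues, and the number of measured neighbours leaves a local change that may be small open.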
